A study of Arabidopsis thaliana with 9 samples.

How the data were processed

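Gene expression was measured in total RNA of whole Arabidopsis thaliana seedlings, on 9 Affymetrix arrays in 3 groups of 3: 0 d, 2 d and 8 d of treatment. Groups and replicate numbers came from the sample titles. Per the labels' protocols, seedlings aged 4 days were moved to medium with both hormones, RNA was extracted with a column kit, and biotinylated cRNA was made by the Affymetrix protocol. The labels also name Cy3 as the label, which does not match biotinylated cRNA, and that was left open.

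The deposited values are probe set signals, an intensity on a linear scale from 7.05 to 27573; MAS5 is named in the submitters' processing notes. The scaling target, the software version and the rule by which probe sets were kept are not given in the sources used here. MAS5 normally scales each array to one target, which makes values relative to the other transcripts on the array, so that a fall in very bright transcripts raises the rest. Detection calls were not used here, so no statement is made on whether a low signal lies above background, and folds that rest on signals under about 100 are imprecise. The table held 10343 probe sets and 23 controls. Probe set numbers span 22743 positions, and the 12400 not in the table were not analysed here. Among the 10343 tested, 99.8% had a one-way F test p under 0.05, which chance and a full array would not give. On simulated unchanged values, such a selection kept 1169 of 22743 probe sets, and 48.3% of those then passed an adjusted p of 0.05 in 2 d vs 0 d, whereas 6 were called when a log2 change of at least 1 was also asked. In that simulation the fold threshold carried most of the protection. Its spreads were drawn from the deposited probe sets, which may have been kept partly for a small spread. The real number of false calls may therefore be higher.

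Signals were set to at least 1, which changed 0 values, and log2 was taken, with no further scaling. Linear models with 1 mean per group were fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without trend or robust prior). P-values are two-sided and adjusted by Benjamini-Hochberg over the 10343 probe sets. A probe set was called at an adjusted p under 0.05 with an absolute log2 change of at least 1. Treatment time and seedling age cannot be separated. On simulated data for 2 d vs 0 d with 10343 probe sets, planted log2 changes of 1, 1.5, 2 and 3 were called in 52%, 96%, 98% and 100% of cases, with 2 false calls. A true change of 1 lies at the fold threshold itself. Only 50 probe sets were changed at each size and the rest were unchanged and unselected, unlike the deposited table. These rates need not hold for the real data.

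Probe sets were named through the array annotation and updated through the reference gene table: 5521 of those tested have 1 gene, 214 have several and 4608 are unnamed here. Of the 5521, 5503 matched the reference and 18 kept the symbol of the array annotation. Only probe sets with 1 gene are named; the named genes number 5485, and for 4624 of them the reference symbol is only the locus. In gene lists each gene has the probe set with the highest mean.

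Genes were named by a rule set before the data were examined. For each comparison it took the 6 largest rises and the 6 largest falls among called genes whose arrays did not overlap between groups and whose higher group was above the median signal. It also took up to 4 called members of each fixed list with those that went against their list, and a short set of callus and hormone genes whatever their result, of which LBD16, GH3.3 and WES1 were measured. Uncalled members of these lists are given as values besides, a choice made after the values were seen. The 35 fixed lists of 432 genes were written from general knowledge by locus before the data were examined. Of these genes 46 were measured with a name, 15 lists had none, 18 had 1 to 4 and only 2 had at least 5, the minimum for a list test. Lists with no measured gene, such as root meristem and shoot meristem regulators, cytokinin oxidases and wound response, were not analysed here. List tests used camera with a preset correlation of 0.01, adjusted over the 2 lists.

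After the annotation was seen, 27 further groups were added: 26 families by gene name, and 69 measured loci of cytosolic ribosomal proteins taken from general knowledge. They were chosen from names and loci, before any gene's value was seen but after the table-wide distribution of changes was known. Their camera tests were adjusted over the 27, and they are reported only in the closing section, apart from the plot of gene groups.

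Alternatives chosen before the data were examined were quantile normalization, centring on the median or the 75th percentile, adding 16 or 64 to the signal, leaving out the dimmest 40%, a trended and robust prior, fitting only the groups compared, array weights, the replicate number as a block, leaving out each array, other thresholds, an estimated correlation, fry, and the mean of a gene's probe sets. Adjusting over the whole span of probe set numbers and centring on the 6 hybridisation controls in the table were added after seeing the data. These 6 controls may themselves have been kept because they differed between the groups. Overlap was set beside 50 simulations of unchanged groups. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading, naming and plotting.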

Results

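Whole Arabidopsis thaliana seedlings were profiled on Affymetrix arrays at an age of 4 days (0 d), and after 2 d or 8 d on Murashige and Skoog medium with 2,4-D and kinetin. 2,4-D is a synthetic auxin and was given at 2.26 µM. Kinetin is a cytokinin and was given at 0.46 µM. Mixtures of an auxin and a cytokinin are used to induce callus, a mass of dividing cells. By the series' own description, the arrays were made so that the effect of FPX, another chemical inducer of callus, could be set beside that of the hormones; FPX arrays were not analysed here. Each time point had 3 arrays, and nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The values were linear probe set signals, with array medians from 445 at 0 d replicate 1 to 546 at 8 d replicate 3 and upper quartiles from 1060 to 1101. The number of arrays limits the precision. The deposited table held 23 control probe sets and 10343 others, and 10323 of these differed between the 3 time points at an unadjusted p under 0.05 in a one-way F test, so the probe sets look to have been chosen on these same arrays. The adjusted p-values are therefore too small, the gene list tests compare a list with other chosen genes, and a gene outside the table was not analysed here. Treatment time and seedling age rose together, and untreated seedlings of the later ages were not analysed here. All changes are differences in mean log2 signal, given with the standard error (SE) from limma and 3 arrays per time point.

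The comparison of 2 d with 0 d asked which transcripts had changed early on the hormones. Some auxin-response genes rose, 1 of 2 measured Aux/IAA genes and 2 of 4 GH3 genes, lists too short for a list test. GH3.3, which encodes an enzyme that joins auxin to amino acids, went from a signal of 1397 ± 246 to 9513 ± 1042 (SD, n = 3), a log2 change of 2.78 (SE 0.14). WES1 (GH3.5), of the same family, rose by 1.76 (SE 0.11), IAA30, of the Aux/IAA family of auxin signalling repressors, by 2.92 (SE 0.22), and LBD16, a transcription factor of lateral root initiation and callus formation, by 1.41 (SE 0.28). The single measured type-A response regulator of cytokinin signalling, RR16, fell by 1.25 (SE 0.26). Of the 26 genes in the G1 and DNA replication list only 2 were measured, and these rose. PRL, a subunit of the replicative helicase, rose by 1.5 (SE 0.18) and ICU2, the catalytic subunit of DNA polymerase alpha, by 1.47 (SE 0.21).

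**Figure D1:**
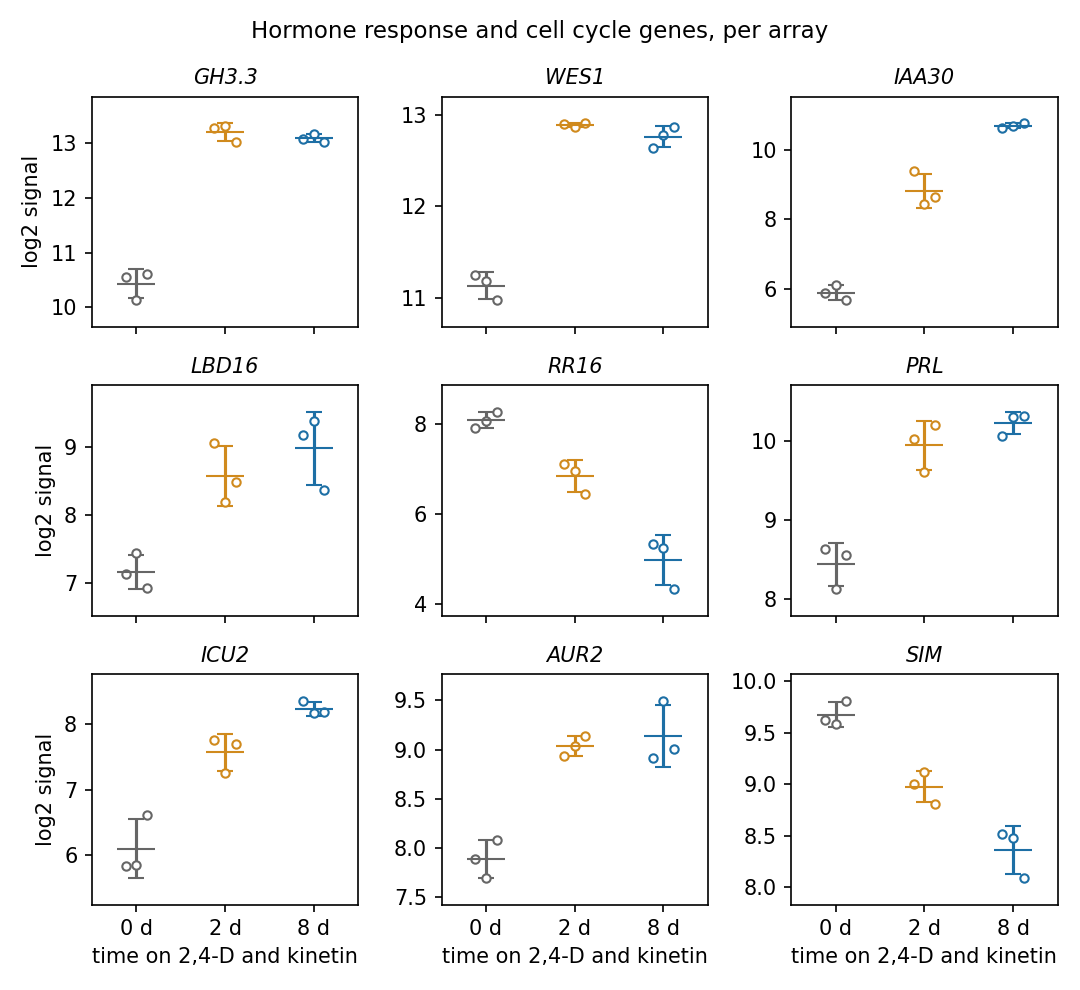
The log2 signal (vertical axes) of 9 genes is plotted for each of the 3 arrays at 0 d, 2 d and 8 d (horizontal axes); circles are arrays, the long horizontal mark is the mean and the bars are 1 SD. GH3.3, WES1, IAA30, LBD16, PRL and ICU2 lie higher at 2 d and 8 d than at 0 d in all 3 arrays, and RR16 and SIM lie lower.

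Among the 20 gene lists fixed before the data were examined that had a measured member, those of ribosome biogenesis, mitosis, expansins and GH3 enzymes also had members that rose at 2 d. Of 6 measured ribosome biogenesis genes, 5 rose, from AT5G14520 at 1.03 (SE 0.13) to AT1G52930 at 1.62 (SE 0.16), and AT5G60990 was at 0.78 (SE 0.12). The median of the 6 was 1.27, against 0.21 for all named genes (camera, adjusted p = 0.0022; adjusted p = 0.348 with an estimated correlation). Without 2 d replicate 1, 3 of the 6 were called, with AT5G14520 at 0.88 and YAO at 0.998, and 4 of the 6 after median centring or with array weights, with AT5G14520 at 0.86 and 0.94. Of 3 Aurora kinases of mitosis, AUR2 rose by 1.15 (SE 0.16), while AUR1 was at 0.89 (called at 1.09 after centring on hybridisation controls) and AUR3 at 0.62; AUR2 was at 0.91 after quantile normalization and 0.98 after median centring, short of the fold threshold. Expansins loosen cell walls. Of the 4 measured genes in the expansin list, EXPB3 rose by 1.64 (SE 0.30) and EXPA4 by 1.35 (SE 0.15). EXPA15 was at 0.84 (called at 1.04 after centring on hybridisation controls) and EXPA8 at -0.26. The table held further expansins outside this list, and EXPA7 of the root hair list fell by 2.44. Of 4 GH3 genes, GH3.17 was at 0.47 and GH3.9 at -0.21, and neither was called.

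Other lists had members that fell or none that passed the test at 2 d. EXPA7, an expansin of root hairs, fell by 2.44 (SE 0.31). UGT73B5 fell by 2.27 (SE 0.27) and UGT73B4 by 1.78 (SE 0.23); both encode glycosyltransferases from the xenobiotic detoxification list, whose other measured member GSTU25 was at -0.30. COR47, a dehydrin, fell by 1.31 (SE 0.19), and COR15A, of the same dehydration list, was at -2.03 (SE 0.97) and was not called. Its log2 signal in 8 d replicate 1 was 2.82, and COR15A was called at 2 d without that array (limma, adjusted p = 0.00047), without 8 d replicate 3 (0.040), with only the 0 d and 2 d arrays (0.00021), after quantile normalization (-2.35) and after adding 16 (-1.88) or 64 (-1.55) to each signal. PORB, an enzyme of chlorophyll synthesis, fell by 1.16 (SE 0.13), though by 0.96 after centring on hybridisation controls, and CHLM, a second chlorophyll gene, was at -0.16. None of 6 photosystem and light-harvesting genes was called by limma, with values from -0.30 (LHCB4.2) to -0.048 (PSAE-1) and 0 of the 6 at an unadjusted p under 0.05 (camera for the list, adjusted p = 0.12; fry, adjusted p = 0.27). RCA, PRK and SBPASE of carbon fixation were at -0.096, -0.066 and -0.20. Not called either were IAA18 (-0.081), YUC2 of auxin synthesis (-0.37), SIM, an inhibitor of cyclin-dependent kinases (-0.70), HCT of lignin synthesis (0.047), FMA of the stomatal lineage (0.38), the clock gene GI (-0.37) and the reference gene GAPC2 (-0.078).

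The largest rises at 2 d among named genes of at least middling signal were in ALPHA-VPE, which encodes a vacuolar processing enzyme, at 4.39 (SE 0.26), and in AT2G19970 at 4.09, AT4G22490 at 3.70, SAG29, a sugar transporter, at 3.63, TBL36 at 3.53 and AT5G37990 at 3.16. The largest falls among such genes were in AT5G54370 at -5.36 (SE 0.29), SBT4.12, a subtilase, at -3.98, AT1G52050 at -3.92, AT3G19430 at -3.91, AT2G41730, from a probe set that may also bind other transcripts, at -3.75 and MSRB9, a methionine sulfoxide reductase, at -3.70. Several of these folds rest on low signals and are imprecise. These were 60.3 for ALPHA-VPE and 67.8 for AT5G37990 at 0 d. At 2 d they were 46.1 for AT5G54370, 64.7 for SBT4.12, 59.0 for AT1G52050 and 53.4 for AT3G19430. In total 1546 of 10343 probe sets were called at an adjusted p under 0.05 and a log2 change of at least 1, with 1008 higher and 538 lower. The median change of all probe sets was 0.19, and the share of higher calls, 65.2%, became 46.7% after quantile normalization, 48.1% after median centring and 81.2% after centring on hybridisation controls, and was 46.9% at a log2 change of at least 2, so which direction prevailed was not settled. Leaving out the dimmest 40% of probe sets gave 703 calls, and adding 64 to each signal gave 965 and ended the calls of ICU2 at 0.93, RR16 at -0.91 and AUR2 at 0.97.

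At 8 d against 0 d, which asked what distinguished seedlings after the longest treatment, photosynthesis and chlorophyll genes fell, and ribosome biogenesis and several auxin-response genes rose. CHLM, a chlorophyll synthesis enzyme, fell by 2.04 (SE 0.13), from a signal of 6570 ± 198 to 1605 ± 250 (SD, n = 3), and PORB by 2.12 (SE 0.13). SBPASE and PRK, enzymes of the Calvin cycle, fell by 2.20 (SE 0.21) and 1.69 (SE 0.23), and RCA was at -0.76 (SE 0.10), short of the fold threshold except after median centring (-1.04). Of 6 photosystem and light-harvesting genes 5 fell, led by PSBY at -1.74 (SE 0.14) and LHCB4.2 at -1.69 (SE 0.16), and PSAE-1 was at -0.97 (SE 0.17), called after centring on the median (-1.25) or 75th percentile, with array weights (-1.09), and without 0 d replicate 3 (-1.08) or 8 d replicate 3 (-1.13). The list's median was -1.35, against 0.46 for all named genes (camera, adjusted p = 0.00076; adjusted p = 0.255 with an estimated correlation), and after quantile normalization 2 of the 6 were called, with LHCB4.1 at -0.94, PSAN at -0.88 and PSBW at -0.80.

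All 6 ribosome biogenesis genes rose at 8 d, from AT5G60990 at 1.30 (SE 0.12) to AT1G52930 at 2.23 (SE 0.16), with a median of 1.84 (camera, adjusted p = 0.0077; adjusted p = 0.255 with an estimated correlation). For all 20 lists and all 3 comparisons, the count adjusted over the list alone equalled the count over all probe sets. IAA30 rose by 4.78 (SE 0.22), GH3.3 by 2.66 (SE 0.14), GH3.17 by 1.71 (SE 0.16), WES1 by 1.63 (SE 0.11) and LBD16 by 1.82 (SE 0.28). Against these, IAA18 fell by 1.15 (SE 0.11), GH3.9 by 1.31 (SE 0.20) and YUC2, of auxin synthesis, by 1.36 (SE 0.16). RR16 fell by 3.11 (SE 0.26) to a signal of 32.9 ± 11.1, so low that its fold is imprecise. ICU2 rose by 2.14 (SE 0.21) and PRL by 1.78 (SE 0.18). AUR2, AUR3 and AUR1 rose by 1.25, 1.2 and 1.07, and fell short of the fold threshold after quantile normalization, at 0.92, 0.77 and 0.87, and after median centring, at 0.98, 0.92 and 0.80. SIM fell by 1.31 (SE 0.14).

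Expansins went both ways at 8 d, and the measured root hair and stomatal lineage markers, 1 of each, fell. EXPA4 rose by 2.30 (SE 0.15), EXPA15 by 2.00 (SE 0.15) and EXPB3 by 2.00 (SE 0.30), whereas EXPA8 fell by 2.16 (SE 0.27). EXPA7 of root hairs fell by 2.53 (SE 0.31), and FMA, a transcription factor of guard cell differentiation, fell by 1.01 (SE 0.24), a call that ended without 8 d replicate 1 (-0.77), with array weights (-0.88), after centring on hybridisation controls (-0.94) and after adding 16 to each signal (-0.85). GSTU25 rose by 1.2 (SE 0.19) and UGT73B4 by 1.16 (SE 0.23), both short of the threshold after median centring, at 0.93 and 0.89 (UGT73B4 also after quantile normalization, at 0.92), and without 8 d replicate 3, at 0.98 and 0.99. UGT73B5 fell by 1.34 (SE 0.27). COR15A fell by 3.04 (SE 0.97), or by 1.57 without 8 d replicate 1, while COR47 was at 0.20 (SE 0.19). HCT was at -0.71, GI at 0.43 and GAPC2 at -0.29, none of them past the fold threshold.

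The largest rises at 8 d among named genes of at least middling signal were in AT3G48510 at 5.11 (SE 0.21), AT4G38410 at 4.98, IAA30, TBL36 at 4.64, AT1G59740 at 4.57 and AT3G27400 at 4.53. The largest falls among such genes were in AT4G33550 at -5.10 (SE 0.21), AT1G73120 at -4.63, AT2G36145 at -4.45, STOMAGEN, a peptide that promotes stomatal formation, at -4.40 (SE 0.53), AT5G44440 at -4.34 and AT1G52100 at -4.21. Over all probe sets the largest rise was 6.16 and the largest fall -5.23. Folds are imprecise for AT3G48510 (72.6 at 0 d) and, by their 8 d signals, for AT4G33550 (80.8), AT1G73120 (90.0), AT2G36145 (93.7), STOMAGEN (34.4) and AT5G44440 (73.4). In total 4502 probe sets were called, 2625 higher and 1877 lower. The median change of all probe sets was 0.40, and the share of higher calls, 58.3%, became 45.8% after quantile normalization, 40.5% after median centring and 63.3% after centring on hybridisation controls. Leaving out the dimmest 40% of probe sets gave 2444 calls, and adding 64 to each signal ended the calls of AUR1 at 0.97, AUR3 at 0.86, YUC2 at -0.83, GH3.9 at -0.68, FMA at -0.57 and UGT73B5 at -0.96.

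**Figure D2:**
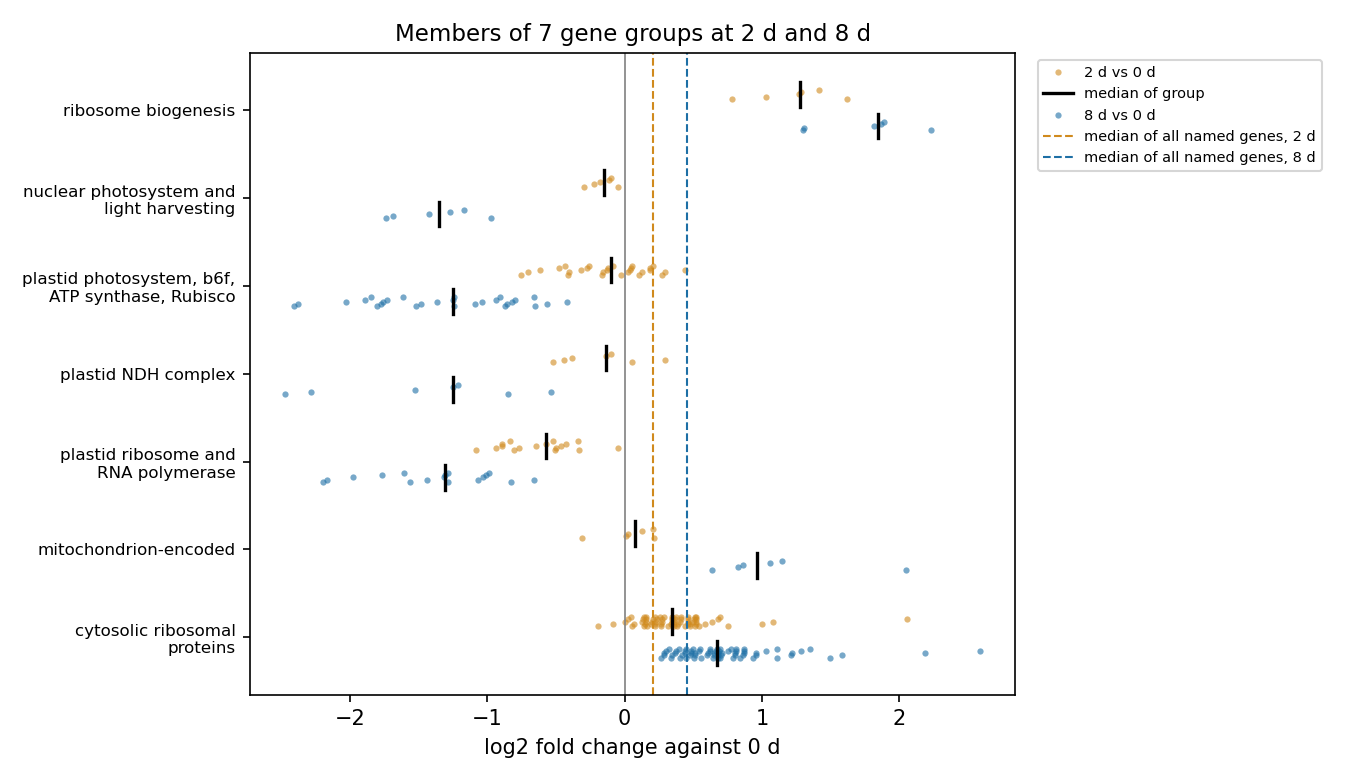
Each point is the log2 fold change against 0 d (horizontal axis) of 1 gene in 1 of 7 groups (vertical axis), at 2 d or 8 d; black bars are group medians and dashed lines the medians of all named genes, 0.21 at 2 d and 0.46 at 8 d. Ribosome biogenesis genes lie above both lines, and the nuclear photosystem and 3 plastid groups reach medians between -1.25 and -1.35 at 8 d; the 5 groups below the top pair were chosen after the annotation was seen and are described in the closing section.

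The comparison of 8 d with 2 d asked what changed between the early and the late time point. Most of the signal decline of the measured photosystem and carbon fixation genes and of CHLM came in this interval, the longer of the 2. PORB had already fallen by 1.16 by 2 d. Saturation, taken up in the closing section, may hide part of an earlier fall of bright genes. SBPASE fell by 2.00 (SE 0.21), CHLM by 1.89 (SE 0.13) and PRK by 1.62 (SE 0.23), and 4 of 6 photosystem genes fell, with PSBY at -1.64 (SE 0.14), LHCB4.2 at -1.39, LHCB4.1 at -1.25 and PSAN at -1.16, while PSBW was at -0.95 and PSAE-1 at -0.93. The photosystem list had a median of -1.2 (camera, adjusted p = 0.00019; adjusted p = 0.255 with an estimated correlation), and 2 of its genes were called after quantile normalization but 6 after centring on the median or on hybridisation controls or without 2 d replicate 1, and 5 with array weights or without 8 d replicate 3. PORB was at -0.96 and RCA at -0.67, neither past the fold threshold. PORB passed it after median centring (-1.06), with array weights (-1.07), after centring on hybridisation controls (-1.08), and without 2 d replicate 3 or 8 d replicate 3 (-1.08).

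Auxin-response genes went different ways between 2 d and 8 d. IAA30 rose by a further 1.86 (SE 0.22) and GH3.17 by 1.23 (SE 0.16), IAA18 fell by 1.07 (SE 0.11; -0.98 without 8 d replicate 1, not called) and GH3.9 by 1.10 (SE 0.20), and GH3.3 and WES1 were at -0.11 and -0.13. GH3.9 was short of the threshold after quantile normalization at -0.82, after adding 16 to each signal at -0.88, and without 2 d replicate 3 at -0.91 or 8 d replicate 2 at -0.98. YUC2 was at -0.99 and LBD16 at 0.41, neither called. YUC2 was called after centring on the median (-1.08), the 75th percentile or hybridisation controls (-1.11), and without 2 d replicate 2 (-1.08), 8 d replicate 1 (-1.07) or 8 d replicate 2 (-1.04). RR16 fell by a further 1.87 (SE 0.26). No ribosome biogenesis, DNA replication or mitosis gene was called by limma between 2 d and 8 d, although an unadjusted p was under 0.05 for 5 of 6, 1 of 2 and 1 of 3; the ribosome biogenesis list had a median of 0.53 (camera, adjusted p = 0.10; adjusted p = 0.471 with an estimated correlation), though it was called by fry (adjusted p = 0.0066) and by camera with array weights (adjusted p = 0.041), and without 2 d replicate 1 its camera adjusted p was 0.030 and AT5G14520 was just past the threshold. After quantile normalization AT5G14520 was called at 1.12. SIM was at -0.61.

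Other list genes also moved between 2 d and 8 d. UGT73B4 rose by 2.95 (SE 0.23), COR47 by 1.51 (SE 0.19), GSTU25 by 1.5 (SE 0.19) and EXPA15 by 1.16 (SE 0.15), and EXPA8 fell by 1.90 (SE 0.27) and FMA by 1.40 (SE 0.24). EXPA4 at 0.95, UGT73B5 at 0.93, GI at 0.81, HCT at -0.76, EXPB3 at 0.36, COR15A at -1.01 (SE 0.97), EXPA7 at -0.096 and GAPC2 at -0.21 were not called. Without 8 d replicate 1 the COR15A value turned to 0.47. EXPA4 was called after quantile normalization (1.22), with array weights (1.10), and without 2 d replicate 1 (1.04) or 8 d replicate 3 (1.10), and UGT73B5 after quantile normalization and without 2 d replicate 1 (1.21), 8 d replicate 1 or 8 d replicate 2 (1.04). Among named genes of at least middling signal, the largest rises were in AT5G54370 at 6.54 (SE 0.29), AT4G33560 at 4.78, AT1G19530 at 4.60, AT2G17850 at 3.87, AT1G52050 at 3.44 and AT4G38410 at 3.39. The 2 d signals of AT5G54370 (46.1), AT4G33560 (48.8), AT2G17850 (65.9) and AT1G52050 (59.0) were low, so their folds are imprecise. The largest falls among such genes were in AT5G48490 at -3.83 (SE 0.40), AT2G36145 at -3.42, AT1G33811 and AT1G52100 at -3.31, AT1G04800 at -3.26 and AT5G44680 at -3.05. Over all probe sets the largest fall was -4.17. In total 2285 probe sets were called, 761 higher and 1524 lower, with a median change of all probe sets of 0.26. The majority depended on the fold threshold, as 33.3% of these calls were higher but 60.9% (4818 higher and 3096 lower) at the adjusted p alone. Leaving out the dimmest 40% of probe sets gave 1363 calls, and adding 64 to each signal ended the calls of RR16 at -0.90, GH3.9 at -0.56, IAA18 at -0.96 and FMA at -0.84.

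The changes at 2 d and at 8 d overlapped, as for GH3.3, IAA30, LBD16, ICU2 and PRL on the higher side and RR16, EXPA7, PORB and UGT73B5 on the lower side. Probe sets called in the same direction at both times numbered 1210, of which 816 were higher and 394 lower, where independent lists of these sizes would share 256 and 97.6. Another 27 were called in opposite directions, where independent lists would give 319. Of the 1210, 230 moved further between 2 d and 8 d and 26 moved back. The log2 changes at both times correlated across probe sets at 0.70, where simulated unchanged groups against shared 0 d arrays gave 0.50, and their covariance was 0.678, where the simulation gave 0.016. Probe sets are not independent replicates, and the 3 arrays at 0 d were too few to split, so part of the excess may come from the shared arrays. In the simulation, however, shared arrays gave only the covariance of 0.016, so their part of the covariance was small there. Its 0 shared calls say little, as few calls can arise when no probe set is changed. How far shared arrays add to the shared calls of changed probe sets was not tested. Adding 64 to each signal gave 734 shared calls, and leaving out the dimmest 40% gave 549.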

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

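The comparisons below rest on tests fixed before the data were examined; the choice of control probe sets to describe was made after their values were seen.

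Between 2 d and 8 d, 27 probe sets switched sides: each was called in opposite directions at the 2 time points against 0 d by limma. Independent lists of the same sizes would give 319. Of these, 16 were lower at 2 d and higher at 8 d, and 11 were higher at 2 d and lower at 8 d; 15 have 1 gene. The widest swing was in AT5G54370, at -5.36 at 2 d and 1.18 at 8 d (SE 0.29). Its signal at 2 d was 46.1, so low that the size of this swing is imprecise. AT1G19530 was at -2.94 and 1.66 (SE 0.21), AT4G33560 at -1.71 and 3.07 (SE 0.35) and AT5G42760 at 1.22 and -1.65 (SE 0.21). Apart from those in the report, these genes were named after their values were seen.

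UGT73B4, a glycosyltransferase of the detoxification list, was at -1.78 at 2 d and 1.16 at 8 d (SE 0.23). Its 8 d call was lost after median centring (0.89), after quantile normalization (0.92) and without 8 d replicate 3 (0.99). The difference between the time points was 2.95, with an adjusted p of 5.5e-06 in limma.

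A pair of hybridisation control probe sets, outside the comparisons, had a higher signal at 8 d than at 0 d: AFFX-BioB-M by 0.275 and AFFX-BioC-3 by 0.473 on the log2 scale. The other 4 of the 6 hybridisation controls were lower, and the median of the 6 was -0.27.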

How the results depend on the processing

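Adjustment over the whole span of probe set numbers and centring on hybridisation controls were chosen after seeing the data. The largest changes named, 36 over the 3 comparisons, kept their call and direction in all 709 alternative values. They had been picked on these same arrays as the largest called changes, far past the fold threshold. Their stability therefore says little about other genes. Over genes, 3281 alternative values kept direction and side of the threshold, 43 passed it anew, 45 no longer passed and 42 changed sign; over lists these were 1812, 62, 37 and 45. Where no reason is given, the cause was not tested. Most sign changes below are of values near 0 that were not called. For lists, the value is the median relative to all genes, except with fry, where it is the plain median, and the change is in the direction of the test, which follows the mean and can differ in sign from the median. Signal over background was not known, which limits what can be said of dim probe sets.

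Quantile normalization gave 631 higher calls at 2 d. It turned LHCB4.1 (0.0037), PSAE-1 (0.080), PSAN (0.012), PSBY (0.035), RCA (0.051), PRK (0.046), GAPC2 (0.068), IQD calmodulin-binding genes (0.057), cytochrome P450 genes (0.12) and ubiquitin-conjugating enzymes (-0.019) at 2 d. At 8 d against 0 d it turned GAPC2 (0.27), alpha expansins (-0.17) and aldehyde dehydrogenases (0.19). At 8 d against 2 d it turned GH3.3 (0.23), WES1 (0.14), YAO (-0.022), EXPA7 (0.064), GAPC2 (0.20), IQD genes (-0.16), calmodulin-like genes (0.047) and bZIP factors (-0.091). Median centring gave 1692 higher calls at 8 d, and turned HCT at 2 d (-0.13), COR47 at 8 d (-0.076), and YAO (-0.059) and bZIP factors (-0.076) between 2 d and 8 d. Centring on hybridisation controls gave 1641 higher calls at 2 d. There it turned IAA18 (0.12), LHCB4.1 (0.022), PSAE-1 (0.15), PSAN (0.082), PSBY (0.10), RCA (0.10), PRK (0.13), CHLM (0.043), GAPC2 (0.12), cytochrome P450 genes (0.19) and ubiquitin-conjugating enzymes (-0.16). Between 2 d and 8 d it turned AUR2 (-0.022), YAO (-0.083), IQD genes (-0.10) and bZIP factors (-0.076). Both centrings shift each array by 1 value, by construction, whereas quantile normalization reshapes each array and moved genes in opposite directions.

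A pseudocount of 64, which shrinks folds of dim probe sets, gave 965 calls at 2 d with 575 higher, 493 higher calls at 8 d against 2 d and an overlap of 734, and turned bZIP factors between 2 d and 8 d (-0.059). Leaving out the lowest 40% tests fewer probe sets and gave 703 calls at 2 d (457 higher, 246 lower), 2444 at 8 d (1211, 1233), 1363 between 2 d and 8 d (333 higher) and an overlap of 549. It turned alpha expansins at 2 d (0.74) and 8 d (1.74) and aldehyde dehydrogenases at 8 d (-0.036), with fewer members. The adjusted p alone gave 6563 (4144 higher, 2419 lower), 9318 (5615, 3703) and 7914 (4818, 3096) calls for 2 d, 8 d, and 8 d against 2 d, with an overlap of 5256. A log2 change of at least 2 gave 241 (113, 128), 1018 (519, 499) and 310 (79, 231), with an overlap of 168. The looser or stricter threshold is the reason.

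Of the 2 lists fixed beforehand that were long enough, with an estimated correlation 0 lists were called in 2 d vs 0 d, 0 in 8 d vs 0 d and 0 in 8 d vs 2 d by camera, where the lowest adjusted p were 0.348, 0.255 and 0.255; of the 27 added groups 0 were called, with lowest adjusted p of 0.195, 0.33 and 0.553. With array weights both fixed lists (2) were called in 8 d vs 2 d, PRK turned at 2 d (0.017) and bZIP factors between 2 d and 8 d (-0.13). Fitting only the compared groups turned IQD genes between 2 d and 8 d (-0.10). With fry, which does not compare a list with other genes, both fixed lists (2) were called in 8 d vs 2 d, and 21, 23 and 19 of the added groups in the 3 comparisons. Its direction was the opposite for mitochondrion-encoded genes (0.073), alpha expansins (-0.26), TRICHOME BIREFRINGENCE-LIKE genes (-0.33) and ubiquitin-conjugating enzymes (0.044) at 2 d. At 8 d it was the opposite for alpha expansins (0.084), TRICHOME BIREFRINGENCE-LIKE genes (-0.79), VPS genes (-0.20), aldehyde dehydrogenases (0.22) and ubiquitin-conjugating enzymes (-0.13). Between 2 d and 8 d it was so for ATG genes (0.071), tetraspanins (0.18) and calmodulin-like genes (0.017).

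Whether the replicate numbers pair the arrays was not settled. Correlations of deviations between arrays of the same number ran from -0.091 to 0.23, and between arrays of different numbers from -0.27 to 0.23. With 3 arrays per group these ranges cannot exclude pairing. With the replicate block, calls numbered 1548, 4503 and 2285, IQD genes turned between 2 d and 8 d (-0.10), PRA1 genes passed at 8 d, and no other call of a named gene or list changed.

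Leaving out each array in turn gave 1497 to 1681 calls at 2 d (967 to 1113 higher, 530 to 568 lower) and 4418 to 4615 at 8 d (2561 to 2691, 1804 to 1924). Between 2 d and 8 d it gave 2162 to 2607 (693 to 929, 1431 to 1678), and the overlap was 1084 to 1355. Called fixed lists numbered 1 to 1, 2 to 2 and 1 to 2, with 2 in 8 d vs 2 d without 2 d replicate 1. Ranges of values that turned were, at 2 d, PSAE-1 -0.15 to 0.046, PRK -0.15 to 0.076, EXPA8 -0.44 to 0.073, HCT -0.043 to 0.10 and ubiquitin-conjugating enzymes -0.17 to -0.096, and for COR47 at 8 d -0.0038 to 0.33. Between 2 d and 8 d they were IQD genes -0.11 to -0.032, bZIP factors -0.14 to 0.017, YAO -0.13 to 0.31, EXPA7 -0.43 to 0.17, ATG genes -0.31 to -0.15, tetraspanins -0.34 to -0.021, COR15A -2.01 to 0.47, GH9 cellulases -0.21 to 0.11 and AUR2 -0.079 to 0.21.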

Other observations

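The 27 groups below were chosen after the annotation was seen, and of the tests in this part, those of the control probe sets, the plastid groups, saturation and dilution were chosen after the result was seen, as were 2 further ways of choosing the brightest probe sets.

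The signals of plastid-encoded genes fell at 8 d. How far the signals of plastid-encoded and mitochondrion-encoded genes follow the amount of their RNA was not tested. Of 28 genes of the photosystems, cytochrome b6f, ATP synthase and Rubisco, 0 were called by limma at 2 d (10 at an unadjusted p under 0.05), with a median of -0.10 (camera, adjusted p = 0.067, lower; 0.668 with an estimated correlation). This list was called at 2 d after median centring (0.046) and without 0 d replicate 1 (0.041), 0 d replicate 3 (0.047), 2 d replicate 2 (0.029) or 2 d replicate 3 (0.032). Of the 28 genes, 18 fell at 8 d, with a median of -1.25 (camera, adjusted p = 9.9e-10; adjusted p = 0.33 with an estimated correlation). Of 17 plastid ribosome and RNA polymerase genes, 1 fell at 2 d, with a median of -0.57 and all 17 below 0 (camera, adjusted p = 5.4e-06; adjusted p = 0.195 with an estimated correlation). At 8 d 14 of these fell, with a median of -1.31, and 5 of 7 NDH complex genes fell, with a median of -1.25 (camera, adjusted p = 2.4e-07 and 0.0021; adjusted p = 0.33 with an estimated correlation for both). Of 6 mitochondrion-encoded genes 3 rose at 8 d, with a median of 0.96 (camera, adjusted p = 0.14). Of 69 cytosolic ribosomal protein loci, 3 rose at 2 d and 11 at 8 d, with medians of 0.35 and 0.68, near the shift of all named genes (camera, adjusted p = 0.0066 and 5.5e-05; adjusted p = 0.668 and 0.493 with an estimated correlation).

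Some enzyme and signalling families had more members that fell. At 8 d, 8 of 20 UGT glycosyltransferases fell and 2 rose, 5 of 9 tau class glutathione transferases fell and 1 rose, 4 of 6 xyloglucan endotransglucosylases fell and 1 rose, and 3 of 5 calmodulin-like genes fell (camera, adjusted p from 0.0085 to 0.046; adjusted p = 0.33 with an estimated correlation for each). The xyloglucan and calmodulin-like calls were lost after median centring (adjusted p = 0.073), with only the groups compared (0.055), without 2 d replicate 1 (0.056) and without 8 d replicate 3 (0.053). The calmodulin-like call was also lost without 8 d replicate 2 (0.053) and with a pseudocount of 64 (0.054), the xyloglucan call after quantile normalization (0.089) and with array weights (0.066), and the UGT and glutathione transferase calls without the dimmest 40% of probe sets (0.48 and 0.16). At 2 d, 4 of 5 calmodulin-like genes, 2 of 5 tetraspanins, 2 of 10 ATG genes and 5 of 20 UGT genes fell, with 2 UGT genes higher (camera, adjusted p from 0.0015 to 0.022; adjusted p = 0.195 with an estimated correlation for each). The UGT call at 2 d was lost without the dimmest 40% (adjusted p = 0.54). The other families were not called by camera at 2 d or 8 d as deposited, nor were the glutathione transferases at 2 d, but some were under alternatives. Without 2 d replicate 2 the glutathione transferases (0.045), PRA1 genes (0.046), ubiquitin-specific proteases (0.046) and bZIP factors (0.042) were called at 2 d; with all arrays and an estimated correlation their adjusted p was 0.426, 0.266, 0.46 and 0.375. So were the glutathione transferases without 2 d replicate 3 (0.045) and, after centring on hybridisation controls, the glutathione transferases (0.029) and bZIP factors (0.038). PRA1 genes were called at 8 d after quantile normalization (0.049) and without 8 d replicate 1 (0.049; adjusted p = 0.33 with all arrays and an estimated correlation). With fry, which asks whether a list's genes move 1 way and does not compare them with other genes, 21 of the 27 groups were called at 2 d and 23 at 8 d, among them GH9 cellulases (adjusted p = 0.00073 at 8 d), NET genes (4.6e-05), TRM genes (1.7e-05), RNA polymerase II subunits (4.8e-05) and mitochondrion-encoded genes (0.00015). The other families' medians at 8 d were 0.084 for alpha expansins, -0.79 for TRICHOME BIREFRINGENCE-LIKE genes, 1.38 for GH9 cellulases, 0.48 for serine carboxypeptidase-like genes, -0.86 for beta glucosidases, -0.20 for VPS genes, -0.72 for PRA1 genes, 0.51 for IQD genes, 0.22 for aldehyde dehydrogenases and -0.80 for cytochrome P450 genes. They were 0.71 for ubiquitin-specific proteases, -0.13 for ubiquitin-conjugating enzymes, 0.88 for RNA polymerase II subunits, 0.99 for NET genes, -0.66 for bZIP factors and 1.23 for TRM genes.

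In the deposited scaling more probe sets were higher than lower against 0 d, at 65.2% of calls at 2 d and 58.3% at 8 d, but these shares were 46.7% and 45.8% after quantile normalization and 48.1% and 40.5% after median centring, 81.2% and 63.3% after centring on hybridisation controls, and at 8 d 49.6% without the dimmest 40%, so the direction is not settled. Brighter scaling of the later arrays as a whole would raise the 17 bacterial and phage controls. Their median change at 8 d was -0.485 (SE 0.108 over probe sets). The 11 polyA spike controls had a median of -0.63 and all were lower, whereas the 6 hybridisation controls had a median of -0.27, with 4 lower. Several of these probe sets measure the same added transcript, so they are not independent replicates. That equal amounts were added is not given in the sources used here. The controls in the table may also have been kept because they differed between the time points. Their shift therefore does not decide on brighter scaling. A loss of signal by a few very bright transcripts, which scaling would turn into gains elsewhere, stays open: the brightest 5% at 0 d lost 224% of what the others gained, but choosing by 0 d favours a loss; chosen by the mean of 0 d and 8 d the share was 468%, while chosen by 8 d neither part gained, and the summed signal of the others fell by 8.32% of the 0 d total. The hormones and seedling age stay open, untested. For each of the 3 comparisons 1 of the 10 splits of the 6 arrays, the real split, gave as many calls (1546, 4502 and 2285), the highest other gave 0, the splits are too few for a share under 0.05, and the table was itself selected on the real groups.

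Signals of plastid and nuclear photosynthesis genes were lower at 8 d. A lower share of all plastid RNA at 2 d would move the plastid groups alike. The change of the ribosome and polymerase group differed from that of the plastid photosystem group by -0.502 (SE 0.121) at 2 d. At 8 d this difference was -0.063 (SE 0.071). The groups were set against each other after their 2 d changes had been seen, so a lower share of plastid RNA stays open. Saturation may hide part of the fall of the brightest genes: across 11 nuclear genes the 0 d signal and the 8 d change correlated at rho = 0.627 (permutation p = 0.045), though genes are not independent replicates. Across 35 plastid genes rho was 0.58 (permutation p = 0.00039). The plastid photosystem and NDH groups had mean log2 signals of only 11.6 at 0 d, against 13.6 for the nuclear photosystem list. A correlation at such signals does not point to saturation in particular. Dilution of green tissue by 1 factor cannot be told apart from saturation, as the SD between nuclear genes was 3.56 times their median SE, a spread that saturation could add. Hormone treatment and age stay open, untested.

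The 2 d replicate 1 array lay 51.7% of the way from 0 d to 8 d, against 38.7% and 41.7% for the other 2 d arrays. Mixing of 8 d RNA into this sample was argued against: over 35 probe sets at least 8 times brighter at 8 d the median share of 8 d RNA was 1.51% (quartiles 0.15% and 6.04%), where the position would need 18.3%. A faster course in these seedlings stays open, as no biological explanation was tested.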
